A study of Homo sapiens with 15 samples.

How the data were processed

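Gene expression was measured with Affymetrix arrays of 22277 probe sets on total RNA from MCF-10A cells, an established line of immortalized, non-tumorigenic human mammary epithelial cells. Per the labels' protocols, RNA was isolated with silica columns 48 hours after retroviral or adenoviral infection and biotin-labelled by the array maker's standard procedure. The labels do not say which virus was used in which part of the study. A knockdown arm held 2 arrays each of a short hairpin RNA (shRNA) vector control, an shRNA against the DNA-binding domain shared by all p63 isoforms (shDBD) and an shRNA against the isoforms with the transactivation domain (shTA). An overexpression arm held 3 arrays each of an empty vector control, the isoform ΔNp63α, which lacks the N-terminal transactivation domain, and the isoform TAp63γ, which carries it. Every one of the 15 arrays was assigned to its group by its label. The labels call the replicates biological; they do not say whether these were separate infections, so p-values measure the spread between these samples.

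The deposited values are log2 expression values per probe set, which the authors made with RMA, per the submitters' processing notes; the version, the background settings and whether all arrays were processed together are not given in the sources used here. Array medians lay between 7.189 and 7.213 in the knockdown arm and between 6.951 and 6.983 in the overexpression arm. Lower quartiles lay between 5.72 and 5.763 and between 5.393 and 5.457, respectively. Upper quartiles overlapped, at 8.804 to 8.839 and 8.715 to 8.807. The arms were therefore treated as normalized separately, and treatments were compared within an arm; levels of both vector controls set against each other cross the arms. RMA equalizes the distributions of the arrays, so a change of most transcripts in the same direction would not be seen, and it compresses differences at low levels. Detection calls were not used here, so a level below the 20th percentile of its arrays was taken as not shown to be above background. An array has no read depth; the number of arrays limits the precision.

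Probe sets were named with the platform annotation. Of the 22277 probe sets, 62 were array controls, 19064 had 1 gene symbol, 1043 had several and 2108 were not listed in the annotation. Entrez identifiers matched 19058 of the single-symbol probe sets to a current gene table, which changed 0 symbols. Each gene was represented by the probe set with the highest mean over the 15 arrays among those with 1 symbol, which gave 11963 genes, 4310 of them with more than 1 probe set. Of 539 called values of named genes, 267 were of genes with more than 1 probe set, and 0 of these had a probe set called in the opposite direction. Genes named as not passing were not part of this check. The transcript of the gene targeted or introduced was not analysed here, so the labels were not checked with it. A signal of some array control probe sets is not reported here. Genomic positions were not used here.

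Differences were tested with limma 3.58.1 in R 4.3.3: a linear model with a mean per group over all 15 arrays (9 residual degrees of freedom), moderated variances with a trend on the mean level (5.87 prior degrees of freedom), two-sided tests and Benjamini-Hochberg adjustment within each comparison at 0.05. Sharing the variance over both arms was chosen because the knockdown arm alone has few degrees of freedom. Gene lists were tested with limma's camera with a preset correlation of 0.01 as the main test, camera with an estimated correlation and fry beside it, adjusted over 21 lists within a comparison. camera asks whether the genes of a list are shifted against all other genes. The lists covered basal, luminal, mesenchymal and fibroblast, immune, and endothelial and adipocyte markers, basement membrane adhesion, desmosomes, squamous differentiation, genes described as p63 targets, the p53 response, the BCL2 family, G1/S and DNA replication, G2/M and mitosis, the epidermal growth factor (EGF) receptor ligands and ERK targets, NF-kB, interferon, Notch, TGF-beta and BMP, hypoxia and glycolysis, sterol and fatty acid synthesis, and the unfolded protein and stress response. Some genes stand in more than 1 list. The lists, the tests, the alternatives and the rule for naming genes were set before the data were examined. The rule took the 10 genes with the largest change in each direction in each comparison with a vector control, and the 5 in each direction in each direct comparison, among called genes whose arrays did not overlap between groups. It added up to 4 called and 2 uncalled members of each list, and the 10 genes that moved most in opposite directions in a knockdown and an overexpression.

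Overlaps between comparisons were set against the number that independent lists would share and tested with Fisher's exact test over genes, which are not independent. Comparisons that share a control were set against 100 simulations of unchanged groups with the same controls. The procedure was tested on simulated data with 11963 genes, the real means and spreads and 200 changed genes in each of 10 draws. For shDBD it recovered 60.4% of changes of 0.5 on the log2 scale, 94.6% of changes of 1 and 99.8% of changes of 2, with 4.93% false calls. For shTA these values were 60.3%, 95.5% and 99.8%, with 5.07% false calls. For ΔNp63α they were 78.8%, 98.2% and 100%, with 5.96%, and for TAp63γ 79.1%, 97.9% and 99.8%, with 4.7%. Simulated noise was independent between genes, with an SD per gene pooled over both arms. Variation shared between genes and a different spread in each arm were therefore not represented.

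RNA quality was taken from the difference between the 3′ and 5′ control probe sets of actin on each array; a larger value points to shorter transcripts. Alternatives were other variance models, array weights, the arms or the groups compared fitted alone, a floor at the 20th percentile of each array, quantile and cyclic loess normalization over all arrays, the dimmer genes left out, other rules for probe sets, a fold threshold of 2, replicate numbers as a block, and each array left out in turn. After the data were seen, a covariate for an axis of variation in the overexpression arm and a fit without 3 arrays were added. Figures were drawn with matplotlib 3.10.9.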

Results

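Transcript levels of 11963 genes were compared in MCF-10A mammary epithelial cells after knockdown or overexpression of variants of p63, a transcription factor of the p53 family that is expressed in basal epithelial cells. The knockdown arm had 2 arrays per group (shRNA vector, shDBD and shTA) and the overexpression arm 3 arrays per group (vector, ΔNp63α and TAp63γ), all taken 48 hours after infection. Values per array ranged from 3.131 to 14.74 on the log2 scale. Replicate arrays correlated over probe sets at 0.9976 to 0.998 in the knockdown arm and at 0.9925 to 0.9979 in the overexpression arm, and the median residual SD per gene was 0.0821 and 0.113, respectively. Changes are given as log2 fold changes ± SE from limma, with n = 2 per group in the knockdown arm and n = 3 in the overexpression arm. Of the lists called with the preset correlation, 8 of 10 held with an estimated correlation for shDBD, 3 of 9 for shTA, 7 of 14 between the hairpins, 8 of 13 for ΔNp63α, 12 of 13 for TAp63γ and 7 of 10 between the isoforms. The camera p-values of lists below are from the preset correlation unless stated. With an estimated correlation the adjusted p-values of the called lists were larger, the smallest being 9.93e-05, so the very small values overstate the evidence. The number of arrays limits the precision, and with 2 arrays per group the spread of a single gene rests mainly on the variance shared over all arrays.

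The comparison of shDBD with its vector asked which genes depend on p63 of any isoform. With shDBD, 36 of 36 measured genes of G2/M and mitosis fell (36 adjusted over the list alone), with a median of −1.78. Among them were HMMR, a spindle-associated hyaluronan receptor (−2.44 ± 0.2), the mitotic checkpoint kinase TTK (−2.41 ± 0.25) and CENPF, a kinetochore protein (−2.26 ± 0.12). Of 34 genes of G1/S and DNA replication, 29 fell (31 adjusted over the list alone) and 0 rose. The replication licensing factor CDC6 fell (−2.02 ± 0.19), as did RRM2, a subunit of ribonucleotide reductase (−1.53 ± 0.11). PCNA, the replication clamp, did not pass (−0.35 ± 0.14, adjusted p = 0.0992). camera called both lists (adjusted p = 6.92e-48 for G2/M and 7.2e-25 for G1/S, and 8.85e-04 for each with an estimated correlation).

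Adhesion genes were also lower with shDBD. Of 29 basement membrane adhesion genes, 16 fell and 2 rose (18 and 2 adjusted over the list alone; camera adjusted p = 3.66e-08). Integrin β4, part of hemidesmosomes, fell (ITGB4, −1.56 ± 0.16), as did the hemidesmosome linker DST (−1.35 ± 0.11) and the laminin chain LAMB3 (−1.24 ± 0.14), whereas LAMB2, another laminin chain, rose by 1.16 ± 0.19. Integrin β1 did not pass (ITGB1, −0.15 ± 0.094, adjusted p = 0.325). Of 38 genes described as p63 targets, 18 fell and 3 rose (20 and 3 adjusted over the list alone; adjusted p = 6.91e-07). The transcription factor SNAI2 fell (−2.07 ± 0.12), as did the growth factor receptor FGFR3 (−1.90 ± 0.11), and the cell-cycle inhibitor CDKN1C rose by 2.51 ± 0.12. Of 23 EGF receptor ligands and ERK targets, 13 fell and 1 rose (the same numbers adjusted over the list alone; adjusted p = 4.46e-05), among them the ligand HBEGF (−1.34 ± 0.16) and the ERK phosphatase DUSP6 (−1.06 ± 0.11).

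Of 27 p53 response genes, 15 rose and 3 fell with shDBD (16 and 5 adjusted over the list alone; adjusted p = 9.85e-05). They included BAX, a pro-apoptotic BCL2 protein (1.49 ± 0.19), and SESN1, a stress-induced inhibitor of mTORC1 (1.32 ± 0.12). Of 37 interferon response genes, 16 rose and 3 fell (18 and 4 adjusted over the list alone; adjusted p = 1.01e-05), led by IFIT1 (2.83 ± 0.19) and IFI44L (1.68 ± 0.12). The vector level of IFI44L lay below the 20th percentile, and its change was 1.58 with values floored there. Of 21 genes of the unfolded protein and stress response, 7 fell and 3 rose (8 and 3 adjusted over the list alone; adjusted p = 0.00341). Those with the largest change were ASNS, which makes asparagine (−2.02 ± 0.11), the kinase-like regulator TRIB3 (−1.79 ± 0.085) and CHAC1, which degrades glutathione (−1.62 ± 0.13), while ATF3 rose by 1.11 ± 0.089 and the chaperone HSPA5 did not pass (−0.23 ± 0.088, adjusted p = 0.0862). Of 19 basal mammary markers, 9 fell and 3 rose (10 and 3 adjusted over the list alone), and of 23 luminal markers, 6 rose and 0 fell (6 and 0 adjusted over the list alone), among them GATA3 (0.90 ± 0.092) and ERBB3 (1.06 ± 0.13). camera called both lists (adjusted p = 0.026 and 0.0368), and neither call held with an estimated correlation (adjusted p = 0.2 and 0.13). The luminal call was also lost without shRNA vector replicate 1 (adjusted p = 0.0613) or shDBD replicate 2 (adjusted p = 0.0549).

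Among single genes, the largest falls with shDBD were in SLC7A11, the cystine importer (−3.25 ± 0.18, 9.51-fold, adjusted p = 7.29e-09), and PHGDH, which opens serine synthesis (−2.75 ± 0.14, 6.71-fold). Among the genes that rose were CYP4B1, a cytochrome P450 (3.50 ± 0.14, 11.3-fold, adjusted p = 9.76e-10), the proteoglycan SRGN (3.25 ± 0.19), ID2, an inhibitor of helix-loop-helix factors (2.88 ± 0.12), the plasma selenoprotein gene SELENOP (2.86 ± 0.26) and the matrix proteoglycan DCN (2.37 ± 0.13). Lists that did not pass were the BCL2 family (adjusted p = 0.0799), desmosome (0.874), squamous differentiation (0.271), Notch (0.0634), sterol synthesis (0.0742), TGF-beta and BMP (0.998), NF-kB (0.874) and hypoxia (0.908). For the TGF-beta and hypoxia lists the median (0.01 and 0.03) was above 0 and the direction of the test down, and the desmosome list had a median of −0.09 and a mean of 0.01. The markers of other cell types did not pass either, with adjusted p = 0.408 for the immune list, in which CD14 rose by 1.27 ± 0.11, 0.115 for the mesenchymal and 0.701 for the endothelial and adipocyte list. In all, 2543 genes changed, 1323 higher and 1220 lower, and 338 of them at least 2-fold, 128 higher and 210 lower. The count was 1650 without shRNA vector replicate 1. The actin 3′ minus 5′ difference was 0.0669 ± 0.0262 (SD, n = 2) with shDBD and −0.0868 ± 0.00983 with the vector.

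The comparison of shTA with its vector addressed the isoforms that carry the transactivation domain. With shTA, 11 of 34 squamous differentiation genes rose and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 3.17e-08). They included S100A7 (2.03 ± 0.17, 4.09-fold) and the calprotectin subunits S100A9 (1.5 ± 0.11) and S100A8 (1.23 ± 0.085), and the protease inhibitor SERPINB3 (1.36 ± 0.12). Of 15 desmosome genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 5.99e-04, and 0.0947 with an estimated correlation). The desmosomal cadherin DSC2 had the largest rise of these (0.68 ± 0.11), and its call was lost without shRNA vector replicate 1 (adjusted p = 0.062). Of 36 genes of G2/M and mitosis, limma called 0 (0 adjusted over the list alone), with a median of 0.03 and a camera adjusted p of 0.54. Of all 11963 genes it called 274 (2.29%), so a count of 0 among 36 does not set this list apart. Of 38 genes described as p63 targets, 4 rose and 0 fell (5 and 0 adjusted over the list alone), among them FGFR3 (0.93 ± 0.11), and that list did not pass (adjusted p = 0.135).

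Genes lowered by shTA included GDF15, a stress-induced cytokine (−1.19 ± 0.11), the smooth muscle gene TAGLN (−1.04 ± 0.12), CHAC1 (−1.01 ± 0.13) and ANGPTL4, an inhibitor of lipoprotein lipase (−0.98 ± 0.11). Of 23 EGF receptor ligands and ERK targets, 5 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 1.52e-04), with PHLDA1 at −0.87 ± 0.11. Of 21 stress response genes, 3 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 3.87e-04). The lists of basement membrane adhesion (5 of 29 fell, 7 adjusted over the list alone), the p53 response (2 of 27 fell, 6 adjusted over the list alone), G1/S (1 of 34 fell, 4 adjusted over the list alone), TGF-beta and BMP (2 fell and 1 rose of 27, 9 and 2 adjusted over the list alone) and NF-kB (2 fell and 1 rose of 25, 2 and 2 adjusted over the list alone) were called down by the preset correlation. These calls did not hold with an estimated correlation, with adjusted p = 0.104, 0.07, 0.103, 0.0939 and 0.167 in that order, and NF-kB was also lost without shRNA vector replicate 1 (0.0582) or shTA replicate 1 (0.0813).

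Among single genes that rose with shTA were TMEM45A (1.63 ± 0.12), the cytochrome P450 CYP1B1 (1.55 ± 0.12), the interleukin-1 receptor IL1R1 (1.5 ± 0.13) and the complement factor CFB (1.48 ± 0.16). In all, 274 genes changed, 172 higher and 102 lower, and 30 of them at least 2-fold. This count depended on the fit: it was 1064 with the arms fitted separately, 90 and 95 without shRNA vector replicate 1 or 2, 131 and 87 without shTA replicate 1 or 2, and 472 without ΔNp63α replicate 3. The actin 3′ minus 5′ difference was 0.102 ± 0.14 (SD, n = 2) with shTA against −0.0868 ± 0.00983 with the vector.

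Tested directly, both hairpins differed in 2197 genes, 1093 higher and 1104 lower with shDBD. These near-even numbers changed order with several settings, among them cyclic loess (1114 and 1083) and quantile normalization (1220 and 1144). All 36 of 36 G2/M genes (36 adjusted over the list alone; camera adjusted p = 2.02e-54) and 29 of 34 G1/S genes were lower with shDBD than with shTA (31 lower and 1 higher adjusted over the list alone; adjusted p = 5.1e-24), as with CENPF (−2.45 ± 0.12) and TOP2A, the mitotic topoisomerase (−2.42 ± 0.11). Of 27 p53 response genes, 18 were higher with shDBD and 2 lower (20 and 2 adjusted over the list alone; adjusted p = 3.43e-10). Of 34 squamous differentiation genes, 13 were lower and 2 higher (16 and 2 adjusted over the list alone; adjusted p = 1.51e-05), among them S100A7 (−2.25 ± 0.17) and the cornified envelope precursor SPRR1B (−2.20 ± 0.13). Of 37 interferon genes, 17 were higher and 2 lower (19 and 2 adjusted over the list alone; adjusted p = 2.1e-06). FGFR3 was lower with shDBD by −2.82 ± 0.11 and SRGN higher by 4.21 ± 0.19. The calls of the basal (adjusted p = 0.0648), basement membrane (0.0757), desmosome (0.19), EGF (0.0703), luminal (0.0622), sterol (0.141) and stress response lists (0.0879) did not hold with an estimated correlation. The count of genes was 1348 without shDBD replicate 1, 1463 without shTA replicate 2 and 3359 with the arms fitted separately.

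Of the genes called with each hairpin, 179 moved in the same direction, 104 up and 75 down, and 18 in opposite directions. Independent lists would share 19 and 10.4 in the same direction. The count in the same direction was 60 and 69 without shRNA vector replicate 1 or 2, 88 and 60 without shTA replicate 1 or 2, and 297 without ΔNp63α replicate 3. Simulated unchanged groups with the same controls shared 0.01 on average. No gene changed in this simulation, so almost none was called, and its count gives no chance level for groups that did change. The fold changes correlated across genes, which are not independent replicates, at 0.39, against 0.5 in the simulation, and their covariance was 0.0287 against 0.00881. The simulated correlation follows from the shared control and equal group sizes. The 2 control arrays could not be split into groups of at least 2, so part of the excess may come from the shared controls. The mean actin 3′ minus 5′ difference was higher with shDBD (0.0669 ± 0.0262, SD, n = 2) and with shTA (0.102 ± 0.14) than with their vector (−0.0868 ± 0.00983). A part of RNA quality in the genes that moved alike was not tested.

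**Figure D1:**
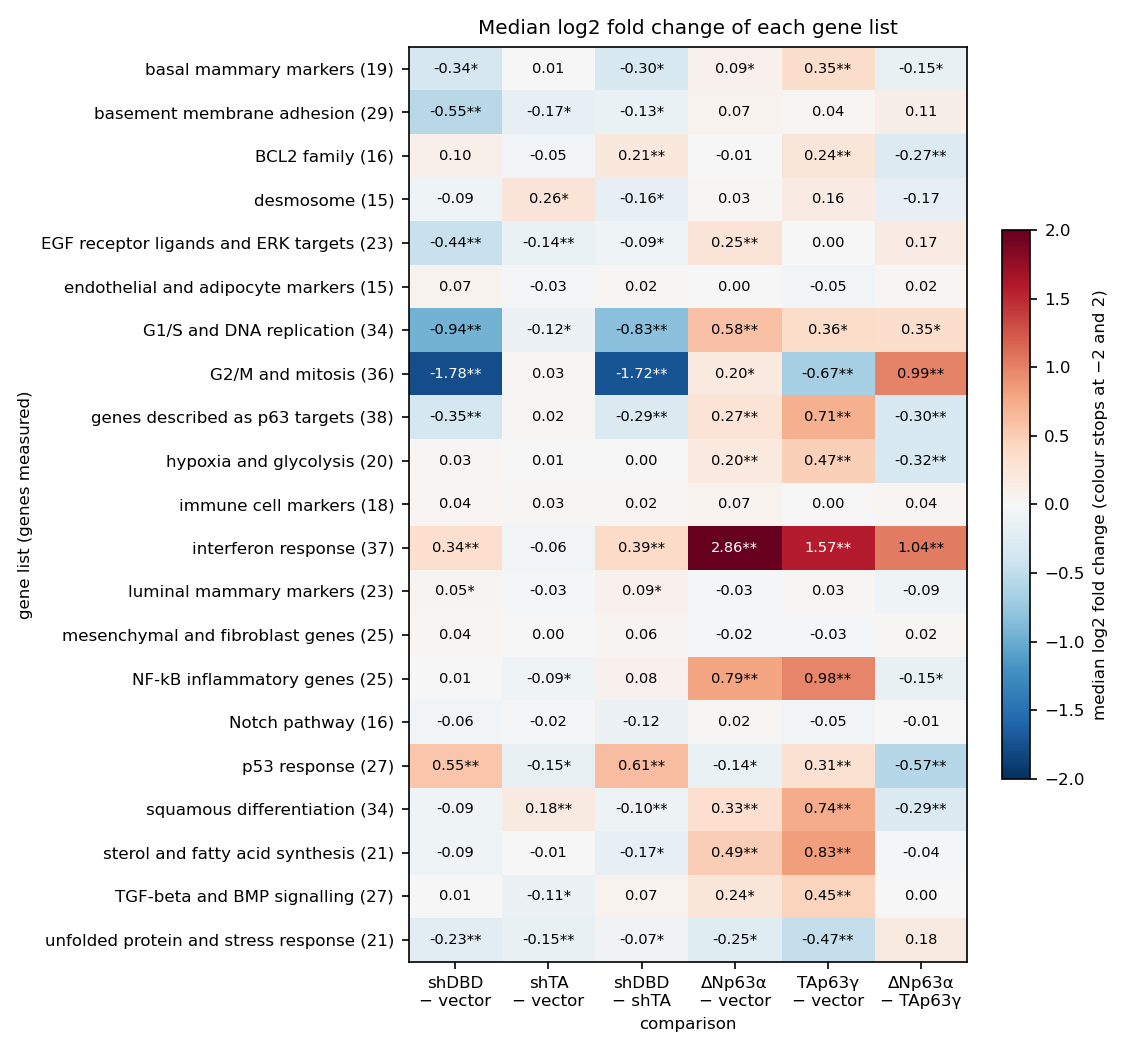
Median log2 fold change of the measured genes of each of 21 gene lists (rows, with the number of genes measured) in 6 comparisons (columns), as colour and number. A single asterisk marks a list called by limma's camera at an adjusted p under 0.05 with the preset correlation, and a double asterisk one that also held with an estimated correlation; the G2/M list stood at −1.78 with shDBD and the interferon list at 2.86 with ΔNp63α.

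The overexpression arm asked which genes each isoform changes. With ΔNp63α, 37 of 37 interferon response genes rose (37 adjusted over the list alone), with a median of 2.86. The camera adjusted p was 9.05e-54, and 9.93e-05 with an estimated correlation. IFIT1 rose by 6.02 ± 0.16 (5.86 with values floored at the 20th percentile of each array), IFI44 rose 51.6-fold (5.69 ± 0.09), IFI27 43.1-fold (5.43 ± 0.089) and ISG15, a ubiquitin-like modifier, 40.4-fold (5.34 ± 0.14). Of 25 NF-kB inflammatory genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 6.63e-13), including the chemokines CXCL8 (3.38 ± 0.18) and CXCL1 (2.61 ± 0.092). Of 34 squamous differentiation genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 1.48e-13), including S100A7 (4.26 ± 0.14), S100A8 (2.96 ± 0.069) and the elastase inhibitor PI3 (2.73 ± 0.13), while SPRR3 did not pass (0.19 ± 0.11, adjusted p = 0.262).

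Replication genes were higher with ΔNp63α. Of 34 G1/S genes, 28 rose and 0 fell (28 and 0 adjusted over the list alone; adjusted p = 3.23e-15), among them the replication factors GINS1 (1.40 ± 0.083) and MCM10 (1.17 ± 0.083). Of 36 G2/M genes, 15 rose and 0 fell (17 and 0 adjusted over the list alone; adjusted p = 1.7e-04, and 0.163 with an estimated correlation). Of 21 sterol and fatty acid synthesis genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 1.23e-08), with the cholesterol pathway enzymes HMGCS1 (2.0 ± 0.17) and SQLE (1.18 ± 0.076). Of 38 genes described as p63 targets, 19 rose and 5 fell (20 and 5 adjusted over the list alone; adjusted p = 1.74e-04), among them FGFR3 (1.94 ± 0.09) and the basal keratin KRT14 (1.90 ± 0.094). Of 23 EGF receptor ligands and ERK targets, 10 rose and 3 fell (11 and 3 adjusted over the list alone; adjusted p = 0.00204), and of 20 hypoxia and glycolysis genes, 9 rose and 2 fell (10 and 3 adjusted over the list alone; adjusted p = 0.00135).

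Of 27 p53 response genes, 11 fell and 2 rose with ΔNp63α (11 and 3 adjusted over the list alone; adjusted p = 0.0108, and 0.111 with an estimated correlation). GDF15 fell (−1.34 ± 0.09), as did the RNA-binding protein gene ZMAT3 (−1.21 ± 0.15), and CDKN1A, the cell-cycle inhibitor p21, did not pass (−0.05 ± 0.13, adjusted p = 0.836). Of 27 TGF-beta and BMP genes, 13 rose and 6 fell (13 and 6 adjusted over the list alone; adjusted p = 0.0127, and 0.111 with an estimated correlation), led by the activin subunit INHBA (3.76 ± 0.16). Of 21 stress response genes, 12 fell and 4 rose (12 and 4 adjusted over the list alone; adjusted p = 0.0108, and 0.0561 with an estimated correlation), with ASNS at −1.31 ± 0.09. Of 19 basal markers, 7 rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.0306). The basal call did not hold with an estimated correlation (adjusted p = 0.21), nor without overexpression vector replicate 3 (0.0591), ΔNp63α replicate 1 (0.0617) or ΔNp63α replicate 2 (0.053). Lists that did not pass were basement membrane adhesion (0.0532), the BCL2 family (0.306), desmosome (0.668), luminal markers (0.467), Notch (0.982), and the immune (0.454), mesenchymal (0.866) and endothelial and adipocyte (0.668) markers.

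Other genes with large changes included TFPI2, a serine protease inhibitor, which rose (6.50 ± 0.11, adjusted p = 1.15e-15), the collagenase MMP1 (5.27 ± 0.13) and the chemokine CXCL14 (5.23 ± 0.15). CLGN, an endoplasmic reticulum chaperone known from the testis, fell (−4.22 ± 0.17, adjusted p = 4.38e-11), and CBS, the first enzyme of transsulfuration, fell 4.93-fold (−2.30 ± 0.15). CLGN stood at 8.90 ± 0.42 (SD, n = 3) with the vector and at 4.67 ± 0.28 with ΔNp63α. It lay between 3.86 and 4.14 on the 6 knockdown arrays, so the overexpression vector stood apart from all other groups, across arms treated as normalized separately. The dimmer group of TFPI2, MMP1 and CLGN lay below the 20th percentile of its arrays and was not shown to be above background, so these sizes are approximate; with values floored at that percentile they were 5.65, 4.18 and −3.78. In all, 3454 genes changed, 1469 higher and 1985 lower, and 327 at least 2-fold, 247 of these higher. With cyclic loess normalization over all arrays, 1725 were higher and 1602 lower. The actin 3′ minus 5′ difference was 0.163 ± 0.0594 (SD, n = 3) with ΔNp63α and 0.17 ± 0.0579 with the vector.

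With TAp63γ, the squamous, p53 and mitotic lists moved. Of 34 squamous differentiation genes, 23 rose and 0 fell (24 and 0 adjusted over the list alone; camera adjusted p = 2.19e-13). S100A7 rose 115-fold (6.85 ± 0.14, adjusted p = 1.29e-14), PI3 by 4.97 ± 0.13 and the cornified envelope gene SPRR2B by 3.59 ± 0.11. Of 27 p53 response genes, 14 rose and 2 fell (15 and 3 adjusted over the list alone; adjusted p = 0.00145), among them the polo-like kinase PLK2 (2.14 ± 0.095), TP53I3 (1.63 ± 0.086), CDKN1A (1.60 ± 0.13) and the ubiquitin ligase MDM2 (1.44 ± 0.1). Of 36 G2/M genes, 29 fell and 1 rose (30 and 1 adjusted over the list alone; adjusted p = 8.74e-10), including HMMR (−2.46 ± 0.16) and the kinetochore motor CENPE (−2.38 ± 0.12), while CDC20 did not pass (−0.05 ± 0.14, adjusted p = 0.804). Of 34 G1/S genes, 18 rose and 3 fell (18 and 3 adjusted over the list alone; adjusted p = 0.0042, and 0.132 with an estimated correlation).

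Of 37 interferon genes, 32 rose and 1 fell with TAp63γ (32 and 1 adjusted over the list alone; adjusted p = 1.29e-19), with IFI27 at 5.06 ± 0.089 and IFIT1 at 3.56 ± 0.16 (3.4 with the floor, its vector level being below the 20th percentile). Of 25 NF-kB genes, 19 rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 7.92e-10), with CXCL8 at 4.17 ± 0.18 and the cytokine IL1B at 3.86 ± 0.1. Of 38 genes described as p63 targets, 25 rose and 5 fell (26 and 5 adjusted over the list alone; adjusted p = 6.43e-08); the epidermal transcription factor ZNF750 rose by 4.20 ± 0.14 (3.26 with the floor, its vector level being below the 20th percentile) and the p53 family member TP73 by 1.81 ± 0.14. Of 20 hypoxia and glycolysis genes, 15 rose and 4 fell (15 and 4 adjusted over the list alone; adjusted p = 3.95e-05), including the glucose transporter SLC2A1 (2.09 ± 0.071). Of 21 sterol synthesis genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 3.88e-06), and of 27 TGF-beta and BMP genes, 15 rose and 5 fell (16 and 5 adjusted over the list alone; adjusted p = 0.00111), with ID2 at 2.72 ± 0.1. Of 19 basal markers, 11 rose and 3 fell (12 and 4 adjusted over the list alone; adjusted p = 1.86e-04), led by the contractile genes TAGLN (4.49 ± 0.097) and ACTA2 (1.69 ± 0.12) and by KRT14 (2.08 ± 0.094). Of 16 BCL2 family genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.0104), among them the pro-apoptotic genes BAX (1.3 ± 0.15) and BAK1 (1.06 ± 0.084). Of 21 stress response genes, 13 fell and 5 rose (13 and 5 adjusted over the list alone; adjusted p = 0.0104), with ASNS at −2.87 ± 0.09.

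Other genes with large changes were the cartilage collagen COL2A1 (5.65 ± 0.18), the cytokine IL36G (5.74 ± 0.17), TFPI2 (6.54 ± 0.11) and the metalloprotease MMP10 (5.57 ± 0.089), which rose with TAp63γ, and CLGN (−4.83 ± 0.17), the matrix gene ECM2 (−4.37 ± 0.14) and SLC7A11 (−4.31 ± 0.15), which fell. After centring on all genes, CLGN, ECM2 and SLC7A11 were 5.14, 2.28 and 2.75 higher in the overexpression vector than in the shRNA vector of the other arm. The dimmer group of COL2A1, TFPI2, MMP10, CLGN and ECM2 lay below the 20th percentile of its arrays, so these sizes are approximate; with the floor they were 5.15, 5.69, 5.27, −3.82 and −3.97. Lists that did not pass were basement membrane adhesion (adjusted p = 0.41), in which FN1, fibronectin, rose by 2.55 ± 0.11 and LAMB1 fell (−1.55 ± 0.11), desmosome (0.0567), EGF receptor ligands and ERK targets (0.627), luminal markers (0.384), Notch (0.866), and the immune (0.962), mesenchymal (0.947) and endothelial and adipocyte (0.962) markers. In all, 5187 genes changed, 2456 higher and 2731 lower, and 1005 at least 2-fold. With cyclic loess, 2636 were higher and 2605 lower. The actin 3′ minus 5′ difference was 0.0771 ± 0.0662 (SD, n = 3) with TAp63γ and 0.17 ± 0.0579 with the vector.

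**Figure D2:**
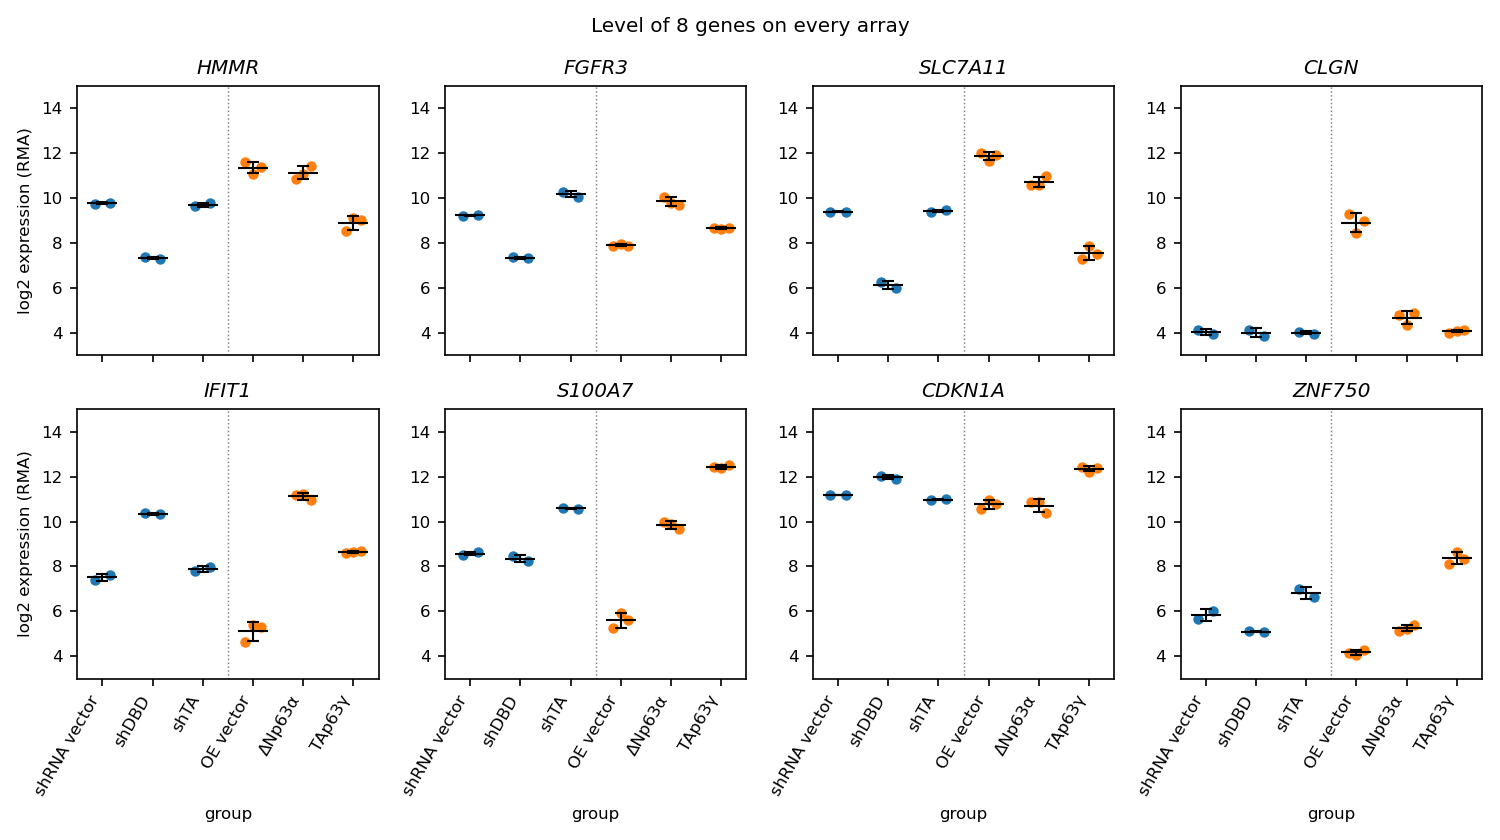
Log2 expression of 8 genes (panels) on each array (points) of the 6 groups, blue for the knockdown and orange for the overexpression arm, with the group mean (horizontal bar) and SD (error bar; n = 2 and n = 3). Medians and lower quartiles differed between the arms, so levels are compared within an arm. CLGN with both isoforms lay below the 20th percentile of its arrays. CLGN stood at 8.90 with the overexpression vector, 4.67 with ΔNp63α, 4.06 with TAp63γ and 3.86 to 4.14 on the knockdown arrays.

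The isoforms were also compared directly. Of 37 interferon genes, 35 were higher with ΔNp63α than with TAp63γ and 0 lower (35 and 0 adjusted over the list alone; camera adjusted p = 2.88e-20), as with IFITM1 (3.33 ± 0.098) and IFI44L (3.27 ± 0.1). Of 36 G2/M genes, 33 were higher with ΔNp63α and 1 lower (33 and 1 adjusted over the list alone; adjusted p = 8.2e-18), as with CENPE (2.54 ± 0.12). Of 27 p53 response genes, 19 were lower with ΔNp63α and 1 higher (19 and 2 adjusted over the list alone; adjusted p = 2.36e-08), including TP53I3 (−2.62 ± 0.086), MDM2 (−1.95 ± 0.1) and CDKN1A (−1.65 ± 0.13). Of 34 squamous genes, 18 were lower with ΔNp63α and 1 higher (18 and 1 adjusted over the list alone; adjusted p = 1.49e-06), including the cornified envelope protein IVL (−2.67 ± 0.088) and S100A7 (−2.59 ± 0.14), whereas S100A8 did not pass (−0.09 ± 0.069, adjusted p = 0.358). Genes described as p63 targets were lower with ΔNp63α in 20 of 38 and higher in 5 (20 and 5 adjusted over the list alone; adjusted p = 4.06e-04), with ZNF750 at −3.11 ± 0.14. TAGLN (−4.61 ± 0.097) and COL2A1 (−5.59 ± 0.18, and −5.12 with the floor) were lower with ΔNp63α. The calls of the basal (adjusted p = 0.164), G1/S (0.0503) and NF-kB lists (0.1) did not hold with an estimated correlation. In all, 4762 genes differed, 2297 higher and 2465 lower with ΔNp63α. The balance turned with cyclic loess, where 2421 were higher and 2283 lower. With values floored at the 20th percentile of each array, 6017 differed, 3516 higher and 2501 lower. The mean floor was 5.12 with ΔNp63α and 5.07 with TAp63γ, so genes at the floor in both stand higher with ΔNp63α by construction. The floored count therefore says nothing about the balance.

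Among genes called with each isoform, 2244 moved in the same direction, 992 up and 1252 down, where independent lists would share 302 and 453, and 256 moved in opposite directions. Simulated unchanged groups with the same controls shared 0. As no gene changed in this simulation, its count gives no chance level for groups that did change. The fold changes correlated across genes at 0.62, against 0.5 in the simulation, and their covariance was 0.161 against 0.00587. The simulated correlation follows from the shared control and equal group sizes. The 3 control arrays could not be split into groups of at least 2, so part of the excess may come from the shared controls.

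**Figure D3:**
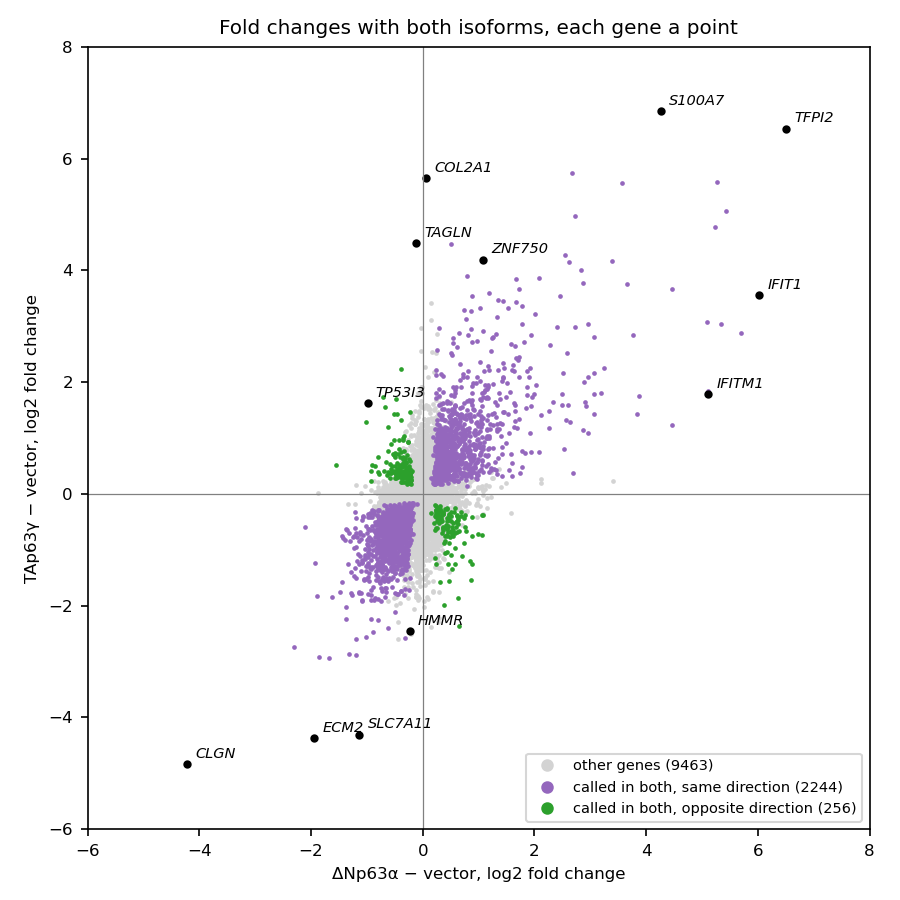
Log2 fold change against the vector with ΔNp63α (x axis) and TAp63γ (y axis) of 11963 genes (points), with 2244 genes called in both in the same direction in purple, 256 called in opposite directions in green and 12 named genes in black. IFITM1 and IFIT1 lie toward ΔNp63α, TAGLN, COL2A1 and ZNF750 toward TAp63γ, and CLGN is low with both.

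Genes that fell in a knockdown were set against those that rose in an overexpression. Of 1220 genes lower with shDBD, 391 were higher with ΔNp63α, where independent lists would share 150 (Fisher's exact p = 1.14e-84 over genes), and of 1323 genes higher with shDBD, 330 were lower with ΔNp63α, where 220 would be shared. FGFR3 (−1.90 ± 0.11 and 1.94 ± 0.09), the plasminogen activator PLAU (−1.40 ± 0.1 and 2.28 ± 0.082), SPRR1B (−1.90 ± 0.13 and 1.82 ± 0.11) and MCM10 (−1.3 ± 0.1 and 1.17 ± 0.083) fell with shDBD and rose with ΔNp63α, and MSLN (1.19 ± 0.13 and −1.17 ± 0.1) did the reverse. Genes also moved alike, 235 up in both and 289 down in both, where 162 and 202 would be shared (Fisher's exact p = 7.5e-10 and 1.68e-11 over genes). Every combination of directions thus exceeded independent lists, so p = 1.14e-84 from Fisher's exact test does not measure opposition alone. Of the 1245 genes called in both, 57.9% were opposite (Fisher's exact p = 2.35e-08 for the signs of these genes). Over all 11963 genes the fold changes with shDBD and ΔNp63α were close to uncorrelated (Pearson's r = −0.0214, Spearman's rho = −0.0608). With shDBD and TAp63γ, 682 genes were opposite and 933 alike, so 42.2% of 1615 were opposite (Fisher's exact p = 2.96e-10 for the signs of these genes). Of the opposite genes, 303 were higher with shDBD, where 302 would be shared, and 379 lower, where 250 would be. Alike were 486 up in both and 447 down in both, where 272 and 279 would be shared. The transcription factor gene ZBED2 (−2.52 ± 0.12 and 2.10 ± 0.095) and the plasminogen activator PLAT (−2.10 ± 0.11 and 2.51 ± 0.087) were among the opposite ones. The opposite count was 432 without shRNA vector replicate 1. With shTA, 77 genes were opposite to ΔNp63α and 84 alike, and 101 were opposite to TAp63γ and 106 alike. The latter opposite genes included TAGLN (−1.04 ± 0.12 and 4.49 ± 0.097), MYL9, a myosin light chain (−0.89 ± 0.14 and 3.41 ± 0.12), and CYP1B1 (1.55 ± 0.12 and −1.39 ± 0.097). After centring on all genes, CYP1B1 was 3.08 higher in the overexpression vector than in the shRNA vector of the other arm. The counts with shTA fell to 26 and 24 without shRNA vector replicate 1, 26 and 27 without shRNA vector replicate 2, 34 and 40 without shTA replicate 1, 25 and 31 without shTA replicate 2, and 50 and 63 without overexpression vector replicate 3, and were 139 and 195 without ΔNp63α replicate 3.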

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

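Several tests in this part were chosen after the results they measure had been seen. These were the tests on levels in the overexpression vector, shDBD as a check of dose, displacement along the shared axis, RNA quality and replicate numbers. The tests on the amino acid response, on interferon genes with the shared axis as a covariate and on other splits were set before they were run. The shared axis and the amino acid list were themselves chosen after earlier results had been seen. A signal also appeared in probe sets that no comparison used. Among 3151 probe sets without a single gene symbol, limma called 369 with shDBD, 37 with shTA, 662 with ΔNp63α and 1071 with TAp63γ.

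Both isoforms lowered 45 genes at least 2-fold. The centred level of these genes was higher in the overexpression vector than in the shRNA vector arrays by a median of 1.26, across arms that were treated as normalized separately. This decides nothing, since the genes were chosen for a high level in the same overexpression vector arrays. A list of other amino acid response genes, 27 of them measured and 2 also in a list used above, was lower with both isoforms, 18 genes falling with ΔNp63α and 21 with TAp63γ (larger camera p = 9e-08; 0.0105 with an estimated correlation). A lower amino acid response may contribute; levels peculiar to the overexpression vector cultures and an effect of p63 cannot be told apart with this single control.

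Interferon response genes rose with both isoforms. A covariate for the shared axis of array variation decides nothing, since its scores sum to 0 within each group by construction. A shift of whole groups along that axis, with linear effects, was argued against. The list mean rose by 0.09 ± 0.05 (SE) per unit of score within groups. Genes outside the list placed ΔNp63α at −0.17 and TAp63γ at 0.65 from the vector, the latter beyond the highest score of 0.44. At the 95% limits of that slope this gives log2 shifts of at most 0.01 and 0.14, against mean rises of 2.88 and 1.60. The list also rose with shDBD (median 0.34, camera adjusted p = 1.01e-05). That would count against a single monotone dependence on the amount of p63 in both arms only if the rise came from lower p63. The targeted transcript was not analysed and a single hairpin was used against all isoforms, so this was not decided. Differences in virus preparation or dose between constructs were not tested and may be the cause, as may the isoforms themselves.

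Within the overexpression groups, 59.3% of the residual variation lay on a single axis, with overexpression vector 1, ΔNp63α 3 and TAp63γ 2 at the same end. Scores on it followed the within-group deviations of the actin 3′ minus 5′ difference over 9 arrays (Pearson's r = −0.84, exact permutation p within groups = 0.0139, adjusted over 2 relations 0.0231; Spearman's rho = −0.68, exact permutation p = 0.0972, adjusted 0.0972), and r was −0.68 without the 2 arrays farthest from the median. The GAPDH difference gave r = −0.88 (exact permutation p = 0.0231, adjusted 0.0231) and rho = −0.82 (exact permutation p = 0.0417, adjusted 0.0834), and r = −0.75 without 2 arrays. RNA quality is therefore a candidate explanation. A batch shared by arrays of the same replicate number was argued against, since arrays of the same number lay on opposite sides for 2 of the 3 numbers; no biological explanation was tested.

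With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 3454 genes for ΔNp63α against its vector, 5187 for TAp63γ and 4762 between the isoforms, and in each case 1 split, the real one, called as many. The highest other counts were 154, 0 and 1. Mixed splits put the difference between the groups into the residual spread, which lowers their counts by construction, so these give no further support. The split with 154 genes grouped ΔNp63α 1, ΔNp63α 2 and overexpression vector 2, which lay on the same side of the shared axis.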

How the results depend on the processing

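All alternatives were planned except the shared axis as a covariate and the fit without 3 arrays, which were chosen after seeing the data. Of 539 values of named genes, 467 kept their direction and call under every alternative run. Of 14973 recomputed values, 315 lost the call and 1 reversed, DSG1 in shDBD against shTA, at 0.005 with values floored at the 20th percentile. The recomputed values include fits without an array of a group not compared, and the fit with the shared axis. Such fits leave the fold change as it was, so the share that lost the call understates the dependence on single arrays. Of 69 called list results, 42 kept the call under every alternative run, 66 of 2001 recomputed values lost it, 24 of them with an estimated correlation, and 0 reversed. limma's fry, which asks whether a list's own genes move one way, passed in 69 of the 69. It also passed in lists that camera did not call, among them the BCL2 family with shDBD (fry adjusted p = 1.12e-04) and the EGF list with TAp63γ (fry adjusted p = 2.48e-05). Passing fry therefore does not set the called lists apart. Without 1 array in turn, gene counts ranged from 1650 to 2968 for shDBD, 87 to 472 for shTA, 1348 to 2588 for shDBD against shTA, 2880 to 3574 for ΔNp63α, 4674 to 5515 for TAp63γ and 4069 to 4857 between isoforms; opposite counts from 502 to 785 (shDBD and ΔNp63α), 432 to 858 (shDBD and TAp63γ), 25 to 139 (shTA and ΔNp63α) and 24 to 195 (shTA and TAp63γ); and alike counts from 60 to 297 for the hairpins and 1892 to 2428 for the isoforms. A group left with 1 array was assumed to vary like the others. At least 2-fold, the counts in the same order were 338, 30, 282, 327, 1005 and 626, then 16, 27, 3 and 4, then 17 and 216, because the threshold is stricter. With all probe sets counted, TAp63γ gave 7859 and the isoforms 7144, since more features were tested. With the arms fitted separately, shTA gave 1064, shDBD against shTA 3359, the opposite counts with shTA 240 and 476 and the alike count of the hairpins 630; the residual SD was lower in the knockdown arm (0.0821 against 0.113). With only the groups compared, shTA gave 1082, shDBD and TAp63γ 1043 opposite, shTA 214 and 501 opposite and the hairpins 638 alike. With array weights, shTA gave 954, the opposite counts were 1212, 1199, 344 and 467 and the alike counts 581 and 3637. With the shared axis, which leaves fold changes as they were because its scores sum to 0 in each group, the counts were 3822 for shDBD, 1271 for shTA and 3441 between hairpins, 1288, 1247, 406 and 676 opposite and 736 alike for the hairpins. The axis was taken from the residuals of the same arrays. Fitting it lowers the residual variation by construction, so higher counts with it give no further support. Without the array of highest actin difference in each overexpression group (overexpression vector 1, ΔNp63α 3 and TAp63γ 2), shTA gave 626, with 171 and 265 opposite and 392 alike. Leaving out overexpression arrays changes no fold change in the knockdown arm, so the hairpin counts moved there through the variance shared over both arms. Beyond this, the spread named and the construction of the axis, the cause of these shifts was not tested. With a replicate block within each arm, shTA gave 150, with 40 and 47 opposite and 98 alike for the hairpins; the other counts stayed within 1.5 times. The numbers share no stated batch: deviations of same-numbered arrays correlated at 0 to 0.07 in the knockdown arm and at −0.63 to 0.48 in the overexpression arm, and 4 of 18 pairings of an array with another group of the overexpression arm matched best at the same number. Cyclic loess moved the share of higher calls with ΔNp63α from 42.5% to 51.8%. The floor gave 3516 higher and 2501 lower between the isoforms, where the level of the floor itself differed between the groups. The planned check of the targeted gene was not run, and background correction was represented by the floor, since the values are already processed; signal near background limits dim genes.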

Other observations

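The comparison of both vector controls and the count of genes also lowered by shDBD were chosen after the results were seen; the amino acid response list was set before its test. Amino acid genes fell with knockdown as well as with overexpression. With shDBD, 19 of the 27 measured genes of the amino acid response list fell and 0 rose (median −0.90, camera p = 7.82e-15, and 0.00115 with an estimated correlation), while with shTA 0 fell and 1 rose (camera p = 0.36). SLC7A11 fell with shDBD (−3.25 ± 0.18) and with TAp63γ (−4.31 ± 0.15), and PHGDH likewise (−2.75 ± 0.14 and −2.60 ± 0.11). Of the 45 genes lowered at least 2-fold by both isoforms, 17 were lower and 9 higher with shDBD, against 1220 lower and 1323 higher of all 11963 genes; the difference between these shares was not tested. CYP1B1 was higher with shDBD (2.04 ± 0.12) and lower with both isoforms (−1.01 ± 0.097 with ΔNp63α). It is among the 45 genes, and after centring it was 3.08 higher in the overexpression vector than in the shRNA vector. Its fall therefore cannot be told apart from a level peculiar to the overexpression vector.

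The control arrays of the arms differed. limma called 9337 of 11963 genes between the overexpression vector and the shRNA vector, a comparison that crosses arms treated as normalized separately. The 171 genes raised at least 2-fold by both isoforms stood lower in the overexpression vector than in the shRNA vector by a median of −0.51 after centring on all genes; they were chosen for a low level in the same overexpression vector arrays.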
